A study of Mus musculus with 8 samples.

How the data were processed

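RNA of CD45+/Sca1+ cells from C57BL/6 mice was measured on 8 Affymetrix mouse 430A arrays, 1 array per sample, in 4 groups of 2: bone marrow, uninjured muscle, injured muscle, and injured muscle of bone marrow transplanted mice. Per the labels' protocols, 1 µg of total RNA was labelled with biotin by a one-cycle method, the RNA was extracted with a micro-scale column kit, and its integrity was examined on a capillary chip. The deposited values are intensities, 1 per probe set, on a linear scale. In the deposited intensity table each array was already scaled so that the trimmed mean, with the lowest and highest 2% of probe sets left out, is about 250 (checked: 250.09 to 250.12 on the 8 arrays). The submitters' processing notes name the Affymetrix software GCOS, with no version or role; how probes were summarised and background was subtracted is not stated there. The labels do not say that replicates are separate animals, so the p-values measure only the spread between these arrays, which may be technical.

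Of 22690 probe sets, 64 control probe sets (spike-ins and 3' and 5' controls) were left out of the tests and described separately, which left 22626. Probe sets were named with the annotation given: 20380 had 1 gene, 691 several genes and 1555 none, and symbols were updated through the gene identifiers of the reference for 20351. Values under 1 were set to 1, and log2(value + 4) was used, where 4 is the 10th percentile of all values. Probe sets with at least 2 of the 8 arrays at or above 38.4, the 40th percentile, were tested: 16289 probe sets, or 9486 of 12393 named genes. For counts and values of genes the probe set with the highest mean over the 8 arrays stands for the gene.

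Groups were compared in limma 3.58.1 under R 4.3.3, with 1 mean per group fitted on all 8 arrays (4 residual degrees of freedom, a median of 4.07 prior degrees of freedom), moderated with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over the tested probe sets of a comparison and a threshold of 0.05. The number of arrays limits the precision: the median SE of a log2 fold change was 0.45. The 4 comparisons, the test, the settings, the gene lists and the rule for named genes were fixed before the data were examined. Where both arrays of the lower group were under 38.4, the fold was computed against that value, with the pseudocount added to both, and is given as "at least"; 38.4 is the filter value and not a detection limit. A printed list median is given also with all values under 38.4 set to it (written "floored") where this moved it by over 1.5 times and by 0.1 or more.

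Named genes were, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap and whose higher mean was at or above 64, the median of all values, and the up to 4 members of each list with the smallest p, with Ptprc, Ly6a and sex-linked genes. With 2 arrays against 2, chance alone keeps the groups apart in 1 direction or the other for 33.3% of genes. Other names are said to be chosen after their values were seen.

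The 26 gene lists hold 593 members, 526 with a probe set. They cover stem and progenitor cells, neutrophil granules, monocytes and macrophages, MHC class II and dendritic cells, B cells, T cells, natural killer and cytotoxic cells, erythroid cells, mast cells with basophils and eosinophils, megakaryocytes, fibroblasts and mesenchymal cells, endothelial cells, skeletal muscle fibres, satellite and myogenic cells, proliferation, interferon response, inflammatory cytokines and chemokines, alternatively activated macrophages, matrix remodelling, immediate early and stress genes, oxidative phosphorylation, glycolysis and hypoxia, ribosomal proteins, p53 targets, homing and adhesion, and lysosome. Each list was tested against all other genes with camera of limma at a preset correlation of 0.01, two-sided, with adjustment over all 104 tests, and again with the correlation estimated for each list. The second form also tests with the 4 residual degrees of freedom of the fit, where the first uses the number of genes. A call lost with it is therefore not due to correlation alone. The endothelial list's estimated correlation after injury was -0.020, yet its unadjusted camera p rose from 1.38e-06 to 0.00641. With the estimated correlation 4 of the 17 lists called for uninjured muscle against bone marrow held, 0 of 17 for injured against uninjured muscle, 0 of 11 for transplanted against untransplanted injured muscle, and 1 of 15 for transplanted injured muscle against bone marrow. Counts "adjusted over the list alone" adjust the limma p-values over the measured members only.

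The position of injured arrays between bone marrow and uninjured muscle was computed on genes chosen in 1 replicate number of both reference groups and measured with the arrays of the other number, so that genes were not chosen and measured on the same arrays. Alternatives were quantile, cyclic loess and median centring normalization, pseudocounts of 1 and at the 25th percentile (17), no filter and a filter at the 60th percentile, no intensity trend, array weights, only the 4 arrays compared, a replicate block, a threshold of 0.01, the mean of all probe sets of a gene, the estimated correlation, a difference of 2 or more for the position, and leaving out each array. A pseudocount at the median (64) was added after the data were seen. A group left with 1 array was assumed to vary like the others. In simulated data of the same size, 34% to 48% of log2 changes of 2 and 92% to 100% of changes of 4 were recovered. False calls were 6 of 118, 10 of 119, 7 of 124 and 7 of 110 in the 4 comparisons. These rates may not hold for groups of unequal spread. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.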

Results

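Gene expression was measured on 8 arrays in cells that carry CD45, a surface protein of blood-derived cells, and Sca1, a surface protein of mouse stem and progenitor cells and of some mature cells. The cells came from C57BL/6 mice aged 6 to 8 weeks and fall into 4 groups of 2 arrays each: bone marrow, uninjured muscle, muscle injured with cardiotoxin (a snake toxin that destroys muscle fibres), and cardiotoxin-injured muscle of mice that had received a bone marrow transplant. The last group is called transplanted injured muscle, and the injured muscle of mice without a transplant is called untransplanted. Time after injury, and whether cells in transplanted mice came from donor or host, are not given in the sources used here. Intensities are given as mean ± SD of the 2 arrays of a group (n = 2), and log2 fold changes with the standard error (SE) of the limma fit.

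The median intensity was 59.1 and 66.4 on the bone marrow arrays, 67.1 and 75.8 on the uninjured muscle arrays, 61.8 and 66.3 on the untransplanted injured arrays, and 56.3 and 59.7 on the transplanted injured arrays. Across probe sets, which are not independent replicates, the correlation between the 2 arrays of a group was 0.929 for bone marrow, 0.837 for uninjured muscle, 0.956 for untransplanted and 0.957 for transplanted injured muscle. The mean profiles of both injured groups had a correlation of 0.951 across probe sets, and those of bone marrow and uninjured muscle 0.848. All 4 pairs of an injured with an uninjured group lay between 0.704 and 0.753. The Gapdh control probe sets at the 3' and 5' ends of the transcript gave ratios of 24.4 and 10.7 in bone marrow, 46.9 and 13.6 in uninjured muscle, and 0.808 to 0.882 on the 4 injured arrays. Beta-actin gave 5.75 and 5.68 in bone marrow, 19.0 and 10.1 in uninjured muscle, and 1.18 to 1.23 on the 4 injured arrays. Ptprc, the gene of CD45, did not pass the test in any of the 4 comparisons and had means of 5367 ± 509 in bone marrow, 5700 ± 1098 in uninjured muscle, 6486 ± 721 in untransplanted and 5924 ± 1018 in transplanted injured muscle. Ly6a, the gene of Sca1, is not named by the probe set annotation used here, so its level was not analysed.

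**Figure D1:**
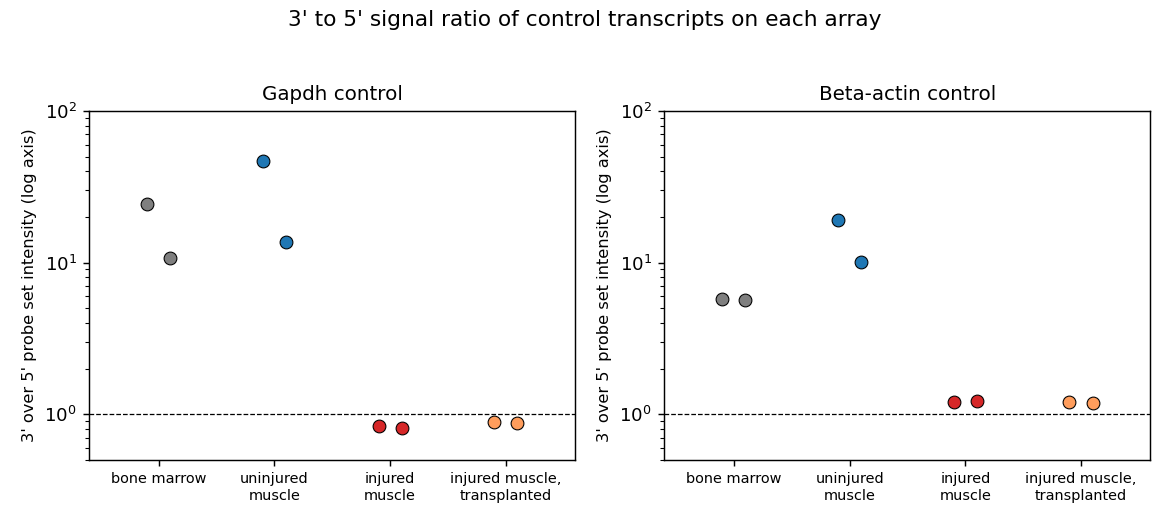
Ratio of the 3' to the 5' control probe set of Gapdh and of beta-actin on each of the 8 arrays (1 point per array, log axis, no unit), by group, with a dashed line at 1. The lowest Gapdh ratio of the 4 uninjured arrays is 10.7 and the highest of the 4 injured arrays is 0.882.

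How CD45+/Sca1+ cells of resting muscle differ from those of the marrow was asked by comparing uninjured muscle with bone marrow. The lists of alternatively activated macrophage (14 of 19 members higher), cytokine and chemokine (16 of 24), endothelial (11 of 18) and matrix remodelling genes (13 of 21) were called higher in the muscle samples and held with an estimated correlation (adjusted p = 0.0376 for the first 3 and 0.0446). The lists of macrophage (15 of 23), fibroblast (20 of 22) and muscle fibre genes (9 of 21) were also called higher, and those of B cells (5 of 20 lower) and proliferation (8 of 26 lower) lower. These 5 calls did not hold with it (adjusted p = 0.0817, 0.101, 0.0844, 0.129 and 0.0626). Retnla, a secreted product of alternatively activated macrophages, had an intensity of 10166 ± 900 in muscle and 109 ± 9.05 in bone marrow (log2 fold change 6.49, SE 0.28, adjusted p = 4.24e-05). Mrc1, the macrophage mannose receptor, had 5282 ± 300 against 154 ± 59.3, and Cxcl1, a chemokine that attracts neutrophils, was at least 38.7-fold higher. Dntt, the enzyme that adds nucleotides at the joints of rearranging antigen receptor genes, had 344 ± 144 in muscle and 4068 ± 50.6 in bone marrow (log2 fold change -3.62, SE 0.46, adjusted p = 0.00325). Ccr9, a homing receptor of lymphoid cells, fell by 3.75 on the log2 scale (adjusted p = 0.000692).

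Of 19 measured genes of the alternatively activated macrophage list, 14 were higher in muscle, none was lower and 5 did not pass the test (17 higher adjusted over the list alone). Besides Retnla and Mrc1 these included Cd163, the haemoglobin scavenger receptor, at 1413 ± 166 against 38.1 ± 3.97, and Folr2, a folate receptor of macrophages, at least 44.6-fold higher. The list was called higher (adjusted p = 5.45e-19, and adjusted p = 0.0376 with an estimated correlation). Of 23 monocyte and macrophage genes, 15 were higher and 8 did not pass (16 adjusted over the list alone). F13a1, coagulation factor XIII of monocytes, had 5246 ± 922 against 412 ± 32.8, and Ms4a7 rose by 2.92 on the log2 scale. That list was called higher (adjusted p = 7e-15; adjusted p = 0.0817 with an estimated correlation). Inflammatory cytokines and chemokines had 16 of 24 members higher, 8 not passing and 19 higher adjusted over the list alone. The monocyte attractant Ccl2 had 1393 ± 165 against 94.7 ± 9.25, and its relatives Ccl7 and Ccl12 were at least 24.5-fold and at least 10.3-fold higher. As a set it was called higher (adjusted p = 2.35e-18; adjusted p = 0.0376 with an estimated correlation).

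Of 22 fibroblast and mesenchymal genes, 20 were higher, none was lower and 2 did not pass (21 adjusted over the list alone), with a median log2 fold change of 3.85, or 2.83 with values under 38.4 set to that value. Col1a2, a chain of collagen I, had 6756 ± 3718 against 109 ± 73.9. Sparc, a matrix glycoprotein, was at least 54.9-fold higher, and Col3a1, collagen III, was at least 77.9-fold higher, with 7756 and 1402 on the 2 muscle arrays. Camera called the list higher (adjusted p = 8.41e-21; adjusted p = 0.101 with an estimated correlation). Of 21 matrix remodelling genes, 13 were higher and 8 did not pass (16 adjusted over the list alone), among them fibronectin (Fn1), at 3604 ± 645 against 713 ± 94.8, and Tgfbi, which rose by 2.67 on the log2 scale. Its adjusted p was 1.66e-12, and adjusted p = 0.0446 with an estimated correlation. Of 18 endothelial genes, 11 were higher and 7 did not pass (14 adjusted over the list alone), with a median of 3.22, or 2.46 with values under 38.4 set to it. Fabp4, a fatty acid carrier of capillaries and fat cells, was at least 122-fold higher, and the water channel Aqp1 had 2434 ± 1195 against 41.5 ± 17.2. That list was called higher (adjusted p = 5.48e-12; adjusted p = 0.0376 with an estimated correlation).

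Skeletal muscle fibre genes had 9 of 21 members higher, 1 lower and 11 not passing (15 higher and 1 lower adjusted over the list alone). Troponin C of fast fibres (Tnnc2) had 1324 ± 6.65 in muscle and was at least 31.3-fold higher, and the myosin light chain Mylpf rose by 3.99 on the log2 scale. The median was 2.87, or 1.60 with values under 38.4 set to it, and the list was called higher (adjusted p = 9.25e-10; adjusted p = 0.0844 with an estimated correlation). Of 12 mast cell, basophil and eosinophil genes, 4 were higher and 8 did not pass (5 higher and 1 lower adjusted over the list alone). The mast cell chymase Cma1 had 2330 ± 102 against 38.5 ± 2.48 and carboxypeptidase A3 (Cpa3) 3056 ± 959 against 232 ± 43.2. This list was called higher (adjusted p = 0.00427; adjusted p = 0.155 with an estimated correlation). Immediate early and stress genes had 7 of 26 members higher and 19 not passing (12 adjusted over the list alone), such as the heat shock protein gene Hspa1a, at 4149 ± 4.62 against 559 ± 85.1, and Atf3, which rose by 2.12 on the log2 scale. Its adjusted p was 1.46e-08, and adjusted p = 0.0844 with an estimated correlation.

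Another 4 lists were called. Megakaryocyte genes had 3 of 11 members higher (3 adjusted over the list alone), with platelet factor 4 (Pf4) at 6484 ± 1466 against 476 ± 256 (list adjusted p = 0.00328; adjusted p = 0.268 with an estimated correlation), a call lost without Muscle replicate 2, where the median was 0.39 against 0.55. Lysosome genes had 5 of 22 higher and 1 lower, the same adjusted over the list alone, with the lipase Lipa up by 1.42 on the log2 scale (list adjusted p = 0.0129; adjusted p = 0.409 with an estimated correlation). That call was lost with cyclic loess normalization, where the median was 0.17 against 0.28, with no intensity trend, with the mean of all probe sets of a gene (0.20), and without Muscle replicate 2 (0.19). Satellite and myogenic genes had 1 of 9 higher, Notch3 (the same adjusted over the list alone), with adjusted p = 0.0186 and adjusted p = 0.332 with an estimated correlation. Notch3 is a receptor also made by vessel wall cells, and the list's call was lost without BM replicate 1 (median 0.82 against 1.04, which was 0.35 floored), without Muscle replicate 2 (0.60), with the filter at the 60th percentile (1.17) and with array weights. T cell genes had 1 of 21 lower, Cd8b1, a chain of CD8 (the same adjusted over the list alone), with adjusted p = 0.0472 and adjusted p = 0.205 with an estimated correlation. The T cell call was lost with quantile normalization (median -0.64 against -0.54), median centring (-0.72), a pseudocount of 1 (-0.55), the filter at the 60th percentile (-0.68), array weights (-0.54), and without BM replicate 2 (-0.39) or Muscle replicate 2 (-0.18).

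Among lists that were lower in muscle, proliferation had 8 of 26 members lower, none higher and 18 not passing (12 adjusted over the list alone), for example the mitotic kinase Cdk1, at 121 ± 1.02 against 391 ± 38.5, and the ubiquitin carrier Ube2c, which fell by 1.75 on the log2 scale. Tested as a set, it was called lower (adjusted p = 4.23e-09; adjusted p = 0.0626 with an estimated correlation). Of 20 B cell genes, 5 were lower and 15 did not pass (9 adjusted over the list alone). Besides Dntt these included the surrogate light chain genes Vpreb1, at 51.1 ± 12 against 707 ± 417, and Igll1, at least 6.05-fold lower. The B cell list was called lower (adjusted p = 5.45e-08; adjusted p = 0.129 with an estimated correlation). Natural killer and cytotoxic genes had 3 of 17 lower and 14 not passing (4 adjusted over the list alone), with the granule protein Nkg7 at 332 ± 55.0 against 1836 ± 429 and interferon gamma (Ifng) at 296 ± 128 against 1204 ± 200. Its adjusted p was 0.000273, and adjusted p = 0.154 with an estimated correlation. Neutrophil granule genes had 1 of 16 lower, lipocalin 2 (Lcn2), at 1222 ± 402 against 4973 ± 859 (the same adjusted over the list alone). That list was called lower (adjusted p = 0.00107; adjusted p = 0.219 with an estimated correlation), except without Muscle replicate 2, where its median was -0.36 against -1.18.

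Of the 9 lists left, none was called. Stem and progenitor genes had 2 of 22 members higher, Tek and Procr, and 2 lower, Flt3 and Meis1 (2 and 3 adjusted over the list alone; median -0.51, adjusted p = 0.0772). The list was called lower with cyclic loess normalization (-0.59), a pseudocount at the 25th percentile (-0.49) or the median (-0.44), no filter, only the 4 arrays compared, and without Muscle_Ctx replicate 1 or 2. Tek is a receptor of endothelial as well as of stem cells. Flt3, a cytokine receptor of multipotent progenitors, had 167 ± 49.9 in muscle and 879 ± 36.5 in bone marrow. MHC class II and dendritic cell genes had 2 higher and 1 lower of 21 (3 and 2 adjusted over the list alone; median 0.09, adjusted p = 0.84), with Irf8 lower and Cd86 higher. Interferon response genes had 2 higher and 3 lower of 21 (3 and 3 adjusted over the list alone; adjusted p = 0.978), with a median of 0.25 but a mean of -0.12. Erythroid genes had 2 of 11 lower, Car2 and Nfe2 (the same adjusted over the list alone), with a median of 0.01, a mean of -0.38 and adjusted p = 0.255, but the list was called lower with the filter at the 60th percentile, where its median was -2.24. For glycolysis and hypoxia none of 21 passed in limma (4 higher and 2 lower at an unadjusted p under 0.05; 1 and 1 adjusted over the list alone), the median was -0.13 and the test pointed upwards (adjusted p = 0.931).

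**Figure D2:**
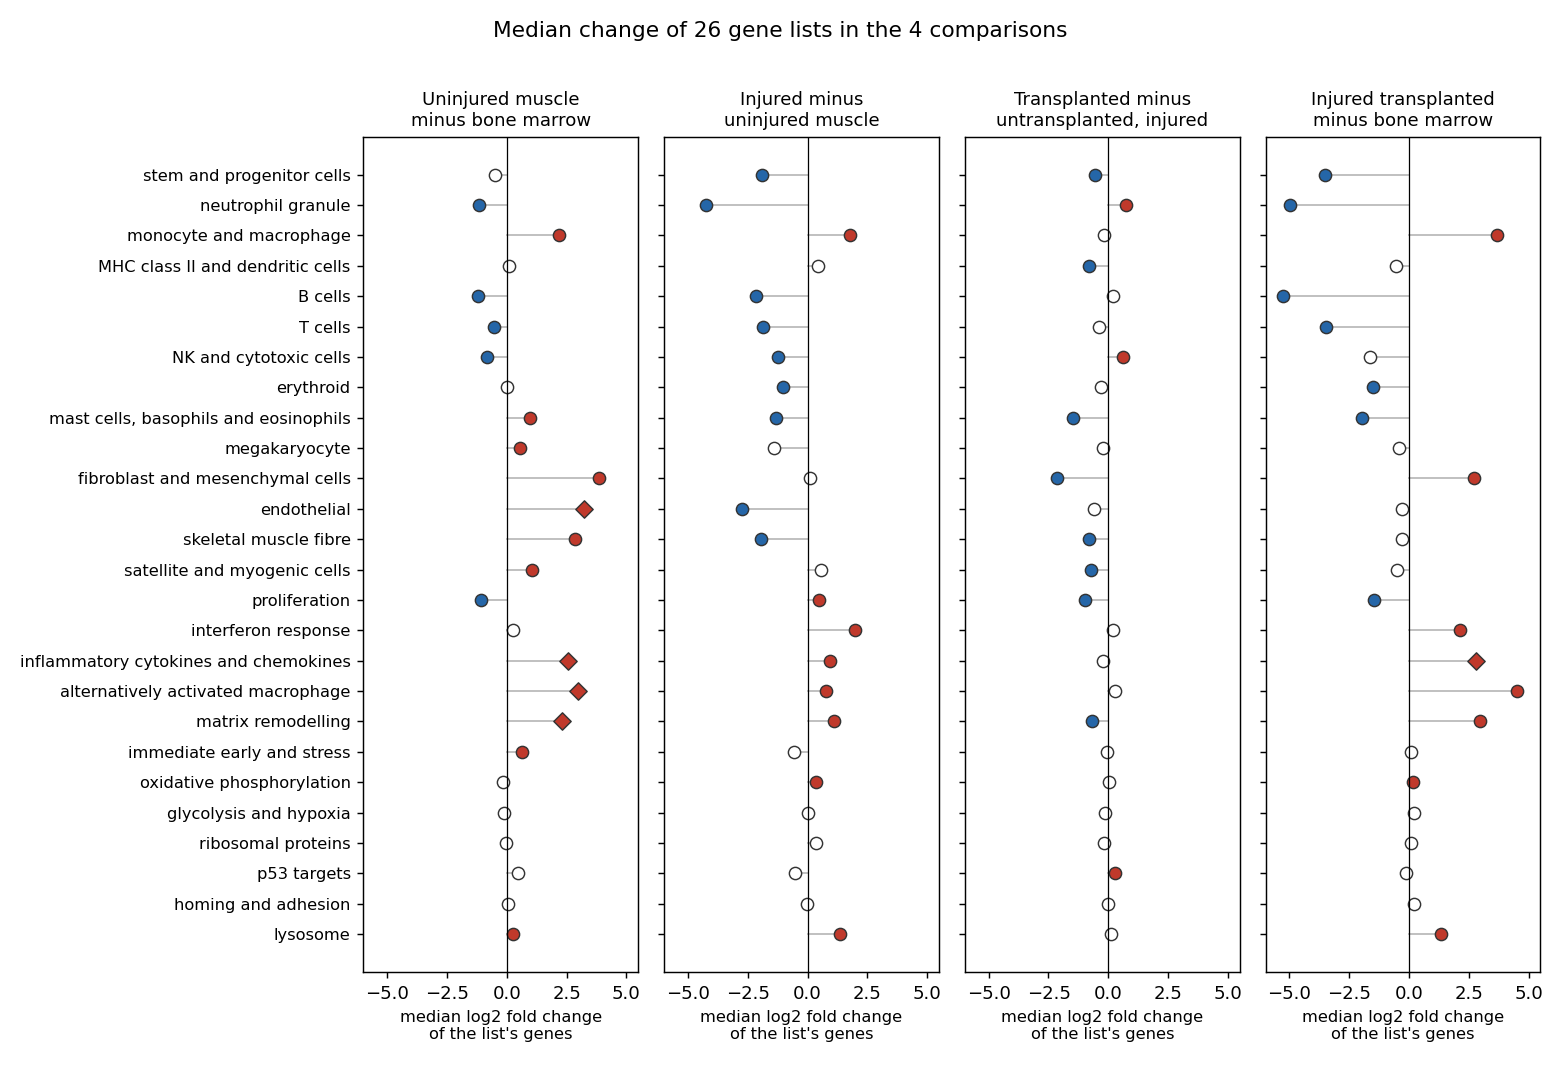
Median log2 fold change of the measured members of 26 gene lists (horizontal axis) in each of the 4 comparisons (panels); filled red or blue points are lists called higher or lower by camera, open points lists not called, and diamonds the calls that held with an estimated correlation. Of 17 lists called for uninjured muscle against bone marrow, 4 held, and of 17 called for injured against uninjured muscle, 0 held.

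In all, 787 of 16289 probe sets were higher in muscle and 204 were lower (543 and 131 genes) by limma at an adjusted p of 0.05, 79.4% of them higher. The median log2 fold change of all probe sets was -0.03, and median centring moved it to -0.21 with 669 higher and 295 lower, 69.4% higher. With array weights 440 were higher and 38 lower, and with only the 4 arrays compared 266 and 22. The counts without BM replicate 1 were 468 and 43, without BM replicate 2 466 and 60, and without Muscle replicate 2 1257 and 1864. The lower count was 387 without Muscle replicate 1, 86 and 84 without Muscle_Ctx replicate 1 or 2, and 98 and 99 without Muscle_Ctx_BMT replicate 1 or 2. Member ranges of lists here and below are over the settings named next. Over the settings with a threshold of 0.05 and 1 probe set per gene, 8 to 21 fibroblast, 7 to 17 macrophage, 7 to 17 cytokine, 8 to 16 alternatively activated macrophage, 5 to 15 matrix remodelling and 5 to 12 endothelial genes were higher. From 1 to 13 B cell, 0 to 12 proliferation, 0 to 6 natural killer and cytotoxic, 0 to 3 T cell and 0 to 3 neutrophil granule genes were lower. Higher and lower members were 0 to 9 and 0 to 5 for lysosome, 0 to 3 and 0 to 8 for MHC class II, 0 to 4 and 0 to 6 for interferon response, and 0 to 2 and 0 to 6 for stem and progenitor genes. From 3 to 10 immediate early and stress genes were higher. The 8 MHC class II, 5 lysosome and 6 interferon response genes lower came without Muscle replicate 2. Each low end was reached with only the 4 arrays compared, array weights or a left-out array. Of the named genes, 32 lost their call without BM replicate 1 and 28 without BM replicate 2.

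What differs in muscle CD45+/Sca1+ cells after injury was asked by comparing untransplanted injured with uninjured muscle. The lists of interferon response (15 of 21 members higher), macrophage (17 of 23) and cytokine genes (10 of 24, with 3 lower) were called higher after injury. Those of neutrophil granule (12 of 16 lower), B cell (11 of 20), T cell (11 of 21), endothelial (12 of 18) and muscle fibre genes (14 of 21) were called lower. Of the 17 lists called in this comparison 0 held with an estimated correlation, the smallest adjusted p = 0.0626 with it. Zbp1, a sensor of nucleic acids induced by interferon, had 1686 ± 275 after injury and 76.8 ± 0.480 before (log2 fold change 4.38, SE 0.29, adjusted p = 0.000372). Trem2, a lipid receptor of macrophages, had 1673 ± 185 against 67.6 ± 90.1. Itgam, a myeloid integrin under 38.4 in bone marrow too, was at least 14-fold higher. Retnla was 325 ± 26.7 after injury against 10166 ± 900 (log2 fold change -4.95, SE 0.28, adjusted p = 0.000162). Ngp, a neutrophil granule protein, had 6384 ± 1794 in uninjured muscle and was at least 148-fold lower after injury.

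These gene groups moved together with the RNA controls: the Gapdh 3' to 5' ratio was 46.9 and 13.6 on uninjured arrays and 0.833 and 0.808 on injured ones. A second probe set, where present, moved the same way in 72.1% of 308 genes called higher (95% exact interval 66.7 to 77) and in 66.3% of 597 called lower (62.4 to 70.1). For 15 and 28 of these it was called the opposite way. Between uninjured muscle and bone marrow the shares were 96.2% of 212 and 85.7% of 35.

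Of 21 interferon response genes, 15 were higher after injury and 6 did not pass (16 adjusted over the list alone). Ifit3 had 2648 ± 232 against 464 ± 80.3, Ifi35 rose by 3.04 on the log2 scale, and the chemokine Cxcl10 by 2.54. The list was called higher (adjusted p = 1.49e-11; adjusted p = 0.0629 with an estimated correlation). Of 23 monocyte and macrophage genes, 17 were higher, 1 lower and 5 did not pass (18 and 1 adjusted over the list alone). Lysozyme (Lyz2) had 20018 ± 1832 against 8216 ± 536, a call lost with quantile normalization, and the immunoglobulin receptor Fcgr1 had 4423 ± 375 against 473 ± 220. This list was called higher (adjusted p = 1.91e-11; adjusted p = 0.104 with an estimated correlation). Cytokines and chemokines had 10 of 24 members higher, 3 lower and 11 not passing (11 and 3 adjusted over the list alone), with Il1b at 10624 ± 293 against 2251 ± 276 and Ccl2 at 8416 ± 30.8 against 1393 ± 165. Il1rn, the antagonist of the interleukin 1 receptor, rose as well, by 3.15 on the log2 scale. The list's adjusted p was 6.02e-05, and adjusted p = 0.0629 with an estimated correlation.

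Lysosome genes had 9 of 22 members higher and 13 not passing (10 adjusted over the list alone), with the protease cathepsin B (Ctsb) at 18212 ± 508 against 6115 ± 2002 (list adjusted p = 8.57e-06; adjusted p = 0.188 with an estimated correlation). Matrix remodelling genes had 9 of 21 higher, 1 lower and 11 not passing (10 and 3 adjusted over the list alone), with tenascin C (Tnc) at 977 ± 40.1 against 70.8 ± 66.2 and the gelatinase Mmp9 lower, at 125 ± 2.35 against 780 ± 62.8. Its adjusted p was 0.000236, and adjusted p = 0.0844 with an estimated correlation. Proliferation genes had 8 of 26 higher, 1 lower and 17 not passing, the same adjusted over the list alone. Ube2c had 564 ± 72.6 against 72.3 ± 23.0, while the replication helicase subunits went both ways, Mcm6 up by 1.46 and Mcm2 at -1.70, each with a second probe set that moved the opposite way. That list's adjusted p was 0.0034 (adjusted p = 0.155 with an estimated correlation), and the call was lost without Muscle replicate 2, with a median of 0.21 against 0.47. Oxidative phosphorylation had 3 of 26 higher and 1 lower, the same adjusted over the list alone, with Sdhb of complex II at 3678 ± 43.9 against 1172 ± 286 (list adjusted p = 0.00834; adjusted p = 0.147 with an estimated correlation). That call was lost with cyclic loess normalization (median 0.22 against 0.34), the mean of all probe sets of a gene (also 0.22) and without Muscle replicate 2 (0.21). Alternatively activated macrophage genes had 7 of 19 higher and 3 lower, the same adjusted over the list alone: galectin 3 (Lgals3) had 18549 ± 203 against 3700 ± 1260, and Retnla and Chil3 were lower. The list's adjusted p was 0.0373 (adjusted p = 0.219 with an estimated correlation), and the call was lost with quantile normalization (median 0.82 against 0.76), cyclic loess normalization (0.81), the filter at the 60th percentile, the mean of all probe sets of a gene, and without Muscle replicate 2 (0.79).

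Of 16 neutrophil granule genes, 12 were lower after injury, 2 were higher and 2 did not pass (13 and 2 adjusted over the list alone), with a median log2 fold change of -4.25, or -3.30 with values under 38.4 set to it. S100a8, a calcium-binding protein of neutrophils, had 112 ± 48.5 against 4992 ± 2190, and myeloperoxidase (Mpo) was at least 40.2-fold lower. As a set it was called lower (adjusted p = 3.35e-06; adjusted p = 0.153 with an estimated correlation). B cell genes had 11 of 20 lower and 2 higher (14 and 2 adjusted over the list alone), with CD20 (Ms4a1) at least 43.7-fold lower and the antibody joining chain gene Jchain, outside the list, at least 59.8-fold lower (list adjusted p = 6.23e-05; adjusted p = 0.188 with an estimated correlation). T cell genes had 11 of 21 lower and none higher (12 adjusted over the list alone), with Lat, an adaptor of the T cell receptor, at 63.1 ± 0.408 against 639 ± 39.1 (list adjusted p = 2.65e-05; adjusted p = 0.0712 with an estimated correlation). Natural killer and cytotoxic genes had 7 of 17 lower and 1 higher (8 and 1 adjusted over the list alone), with the chemokine Ccl5 at 300 ± 44.8 against 1485 ± 421 (list adjusted p = 0.00502; adjusted p = 0.205 with an estimated correlation).

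Endothelial genes had 12 of 18 members lower, none higher and 6 not passing (14 adjusted over the list alone), with the growth factor receptor Kdr at 71.1 ± 1.27 against 1503 ± 718 and Fabp4 at 445 ± 57.8 against 5311 ± 1711. Camera called the list lower (adjusted p = 4.94e-06; adjusted p = 0.0626 with an estimated correlation). Skeletal muscle fibre genes had 14 of 21 lower, none higher and 7 not passing (15 adjusted over the list alone), with Tnnc2 at 109 ± 17.4 against 1324 ± 6.65 (list adjusted p = 6.38e-06; adjusted p = 0.15 with an estimated correlation). Stem and progenitor genes had 13 of 22 lower and 1 higher, the same adjusted over the list alone. Gata2, a transcription factor of stem and mast cells, had 57.4 ± 12.6 against 641 ± 32.2, Myb was at least 9.40-fold lower, and Runx1 was the member that rose. That list's adjusted p was 0.000158, and adjusted p = 0.0698 with an estimated correlation. Mast cell, basophil and eosinophil genes had 5 of 12 lower (6 adjusted over the list alone), with Cpa3 at 824 ± 82.5 against 3056 ± 959. Its adjusted p was 0.0131 (adjusted p = 0.188 with an estimated correlation), and the call was lost without Muscle replicate 2, with a median of -1.49 against -1.31 (-0.72 floored). Erythroid genes had 2 of 11 lower, Nfe2 and Tfrc, whose other probe set moved the opposite way (the same adjusted over the list alone), with adjusted p = 0.0496 and adjusted p = 0.203 with an estimated correlation. That call was lost with quantile normalization (median -0.86 against -1.04, which was -0.61 floored), cyclic loess normalization (-0.69), a pseudocount of 1 (-1.07), no filter, the filter at the 60th percentile (-1.38) and array weights. It was also lost without BM replicate 1 or 2, Muscle replicate 1 (-1.24), Muscle replicate 2 (-1.38) or Muscle_Ctx replicate 2 (-1.11).

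Fibroblast genes were not called as a list after injury: 6 of 22 were higher, 3 lower and 13 did not pass, the same adjusted over the list alone (median 0.11, adjusted p = 0.063), with Bgn at 2375 ± 376 against 430 ± 1.2 and Thy1 lower. That list was called higher without Muscle replicate 1 (median 1.13), with the mean of all probe sets of a gene (0.42) and with a pseudocount at the 25th percentile (0.09) or the median (0.05). MHC class II genes had 2 of 21 higher, the same adjusted over the list alone (median 0.45, adjusted p = 0.0529), with H2-Aa at 18457 ± 1874 against 5505 ± 1504. That list was called higher with the replicate block, median centring (0.59), no filter, the mean of all probe sets of a gene (0.71), and without Muscle replicate 2 (0.95) or Muscle_Ctx replicate 2 (0.47). Megakaryocyte genes had 3 of 11 lower, the same adjusted over the list alone, including von Willebrand factor (Vwf), which endothelial cells also make (median -1.39, -0.65 floored; adjusted p = 0.235). Satellite and myogenic genes had 1 of 9 lower, Notch3 (the same adjusted over the list alone), with a median of 0.56 but a mean of -0.14 (adjusted p = 0.733), and a floored median of -0.22.

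In all, 1973 of 16289 probe sets were higher after injury and 2262 lower (804 and 1413 genes) by limma at an adjusted p of 0.05, 46.6% of them higher. The median log2 fold change of all probe sets was -0.14, and median centring moved it to 0.00 with 2295 higher and 1762 lower, 56.6% higher. The lower count was 1172 with array weights, and with only the 4 arrays compared the counts were 1044 and 1027. Without Muscle_Ctx replicate 1 they were 617 and 706, without Muscle_Ctx replicate 2 609 and 844, and without Muscle replicate 2 3287 and 2780. In member ranges, 5 to 20 macrophage, 9 to 17 interferon response, 7 to 13 cytokine and 1 to 8 proliferation genes were higher. From 4 to 14 T cell, 7 to 14 endothelial, 6 to 15 muscle fibre and 6 to 13 stem and progenitor, 4 to 9 natural killer and cytotoxic, 2 to 5 mast cell, 1 to 3 megakaryocyte and 0 to 3 erythroid genes were lower. Higher members were 3 to 10 for alternatively activated macrophage, 5 to 12 for matrix remodelling, 5 to 12 for lysosome, 3 to 7 for oxidative phosphorylation and 1 to 7 for MHC class II genes, with the 7 without Muscle replicate 2. Fibroblast genes had 2 to 9 higher and 0 to 7 lower. The 2 and 0 came without either Muscle_Ctx array and the 7 without Muscle replicate 2. Of the named genes, 26 and 23 lost their call without Muscle_Ctx replicate 1 or 2.

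Whether the cells of injured muscle differ in mice with a bone marrow transplant was asked by comparing transplanted with untransplanted injured muscle. In the fit on all 8 arrays 4 probe sets passed as higher and 37 as lower (369 and 756 with only the 4 arrays compared), and 2 granzymes of cytotoxic lymphocytes were among the higher ones. The lists of mast cell (3 of 12 members lower), fibroblast (2 of 22), MHC class II (2 of 21) and muscle fibre genes (3 of 21) were called lower. Of the 11 lists called in this comparison 0 held with an estimated correlation (adjusted p = 0.0626, 0.106, 0.205 and 0.155 for these 4). Granzyme A (Gzma) had 1660 ± 0.933 with a transplant and 79.5 ± 7.98 without (log2 fold change 4.32, SE 0.37, adjusted p = 0.0123), and granzyme B (Gzmb) 1319 ± 103 against 126 ± 16.7 (3.35, SE 0.30, adjusted p = 0.0123). The mast cell proteases Cma1, at 79.6 ± 17.6 against 1380 ± 66.6, and Cpa3, at 54.7 ± 1.23 against 824 ± 82.5, were lower (log2 fold changes -4.07, SE 0.30, and -3.82, SE 0.33; adjusted p = 0.0123 for both). For these 4 genes both arrays of 1 group lay above both arrays of the other.

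Natural killer and cytotoxic genes had 2 of 17 members higher, Gzma and Gzmb, and 15 not passing (6 higher adjusted over the list alone). Nkg7 had 236 ± 5.45 against 58.7 ± 2.97, with adjusted p = 0.0648. Tested as a set, it was called higher (adjusted p = 6.21e-09; adjusted p = 0.0712 with an estimated correlation). Rgs1, a regulator of chemokine receptor signalling, rose from 3331 ± 60.1 to 9133 ± 644 (log2 fold change 1.45, SE 0.19, adjusted p = 0.0354), and Txk, a kinase of T and natural killer cells, was at least 1.70-fold higher. Neutrophil granule genes had 0 of 16 passing in limma (0 adjusted over the list alone, 4 higher at an unadjusted p under 0.05), with a median of 0.73 that was 0 with values under 38.4 set to it. That list was called higher (adjusted p = 0.0025; adjusted p = 0.247 with an estimated correlation). The p53 targets had 0 of 16 passing in limma (0 adjusted over the list alone, 1 higher at an unadjusted p under 0.05), with a median of 0.27, adjusted p = 0.0295, and adjusted p = 0.155 with an estimated correlation. The p53 call was lost without Muscle_Ctx_BMT replicate 1 (median 0.18), Muscle_Ctx replicate 1 (0.25) or Muscle_Ctx replicate 2 (0.41).

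Mast cell, basophil and eosinophil genes had 3 of 12 members lower, none higher and 9 not passing (5 adjusted over the list alone): Cma1, Cpa3 and Mcpt4, which was at least 11.3-fold lower. The list was called lower (adjusted p = 6.81e-09; adjusted p = 0.0626 with an estimated correlation). Fibroblast and mesenchymal genes had 2 of 22 lower and 20 not passing (15 adjusted over the list alone; 19 lower and 1 higher with only the 4 arrays compared), with a median log2 fold change of -2.16. Those passing were Bgn, at 531 ± 36.2 against 2375 ± 376, and Serpinf1, a secreted inhibitor of vessel growth, at 160 ± 5.84 against 876 ± 16.2. Col5a1, at 271 ± 11.8 against 1634 ± 184, had adjusted p = 0.0648. As a set it was called lower (adjusted p = 1.28e-19; adjusted p = 0.106 with an estimated correlation). Matrix remodelling genes had 2 of 21 lower and 19 not passing (2 higher and 5 lower adjusted over the list alone): Fn1, at 987 ± 8.08 against 3829 ± 73.7, and periostin (Postn), at 207 ± 11 against 2882 ± 83.0. Mmp12, a macrophage elastase, had 1780 ± 289 against 453 ± 11.9 (adjusted p = 0.0677). That list's adjusted p was 0.0129, and adjusted p = 0.155 with an estimated correlation.

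MHC class II and dendritic cell genes had 2 of 21 members lower and 19 not passing (7 adjusted over the list alone), the antigen-presenting chains H2-Eb1, at 1799 ± 282 against 9196 ± 828, and H2-Aa, at 5458 ± 361 against 18457 ± 1874. Camera called the list lower (adjusted p = 4.15e-09; adjusted p = 0.205 with an estimated correlation). Skeletal muscle fibre genes had 3 of 21 lower (5 adjusted over the list alone), Tnnc2, Mylpf and Myl1, at no more than 39.0 ± 3.46 with a transplant. The median of -0.80 became 0 with values under 38.4 set to it (list adjusted p = 4.33e-05; adjusted p = 0.155 with an estimated correlation). For proliferation 0 of 26 passed in limma, 13 were lower adjusted over the list alone and 15 at an unadjusted p under 0.05, for example cyclin B2 (Ccnb2), at 105 ± 20.6 against 434 ± 26.3 (adjusted p = 0.0578). The proliferation list was called lower (adjusted p = 6.9e-12; adjusted p = 0.0541 with an estimated correlation). Satellite and myogenic genes had 0 of 9 passing in limma, 2 lower adjusted over the list alone and 3 at an unadjusted p under 0.05 (list adjusted p = 0.0025; adjusted p = 0.219 with an estimated correlation), a call lost with the filter at the 60th percentile (median -0.42 against -0.72, which was also -0.42 floored). Stem and progenitor genes had 0 of 22 passing in limma and 0 adjusted over the list alone, with 1 higher and 5 lower at an unadjusted p under 0.05 (median -0.57, -0.09 floored; adjusted p = 0.0371; adjusted p = 0.155 with an estimated correlation). The stem cell call was lost with quantile normalization (-0.44), with only the 4 arrays compared, with the replicate block, and without Muscle_Ctx_BMT replicate 1 (-0.49) or Muscle_Ctx replicate 1 (-0.44).

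Monocyte and macrophage genes were not called as a list: 1 of 23 was lower, F13a1, at 1974 ± 267 against 7322 ± 212 (2 adjusted over the list alone; median -0.16, adjusted p = 0.158). Alternatively activated macrophage genes had 0 of 19 passing in limma (3 higher and 5 lower adjusted over the list alone, 4 and 5 at an unadjusted p under 0.05), with a median of 0.28 but a mean of -0.13 (adjusted p = 0.913). Inflammatory cytokines and chemokines had 0 of 24 passing in limma (2 lower adjusted over the list alone, 1 higher and 4 lower at an unadjusted p under 0.05; median -0.22, -0.12 floored; adjusted p = 0.149). Il6 had 157 ± 26.7 against 568 ± 162 (adjusted p = 0.135). The lists of T cells (median -0.39, 0 floored, adjusted p = 0.359), B cells (0.18, 0 floored, adjusted p = 0.795), endothelial cells (-0.58, -0.13 floored, adjusted p = 0.461), interferon response (0.19, adjusted p = 0.227) and lysosome (0.11, adjusted p = 0.139) were not called either.

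**Figure D3:**
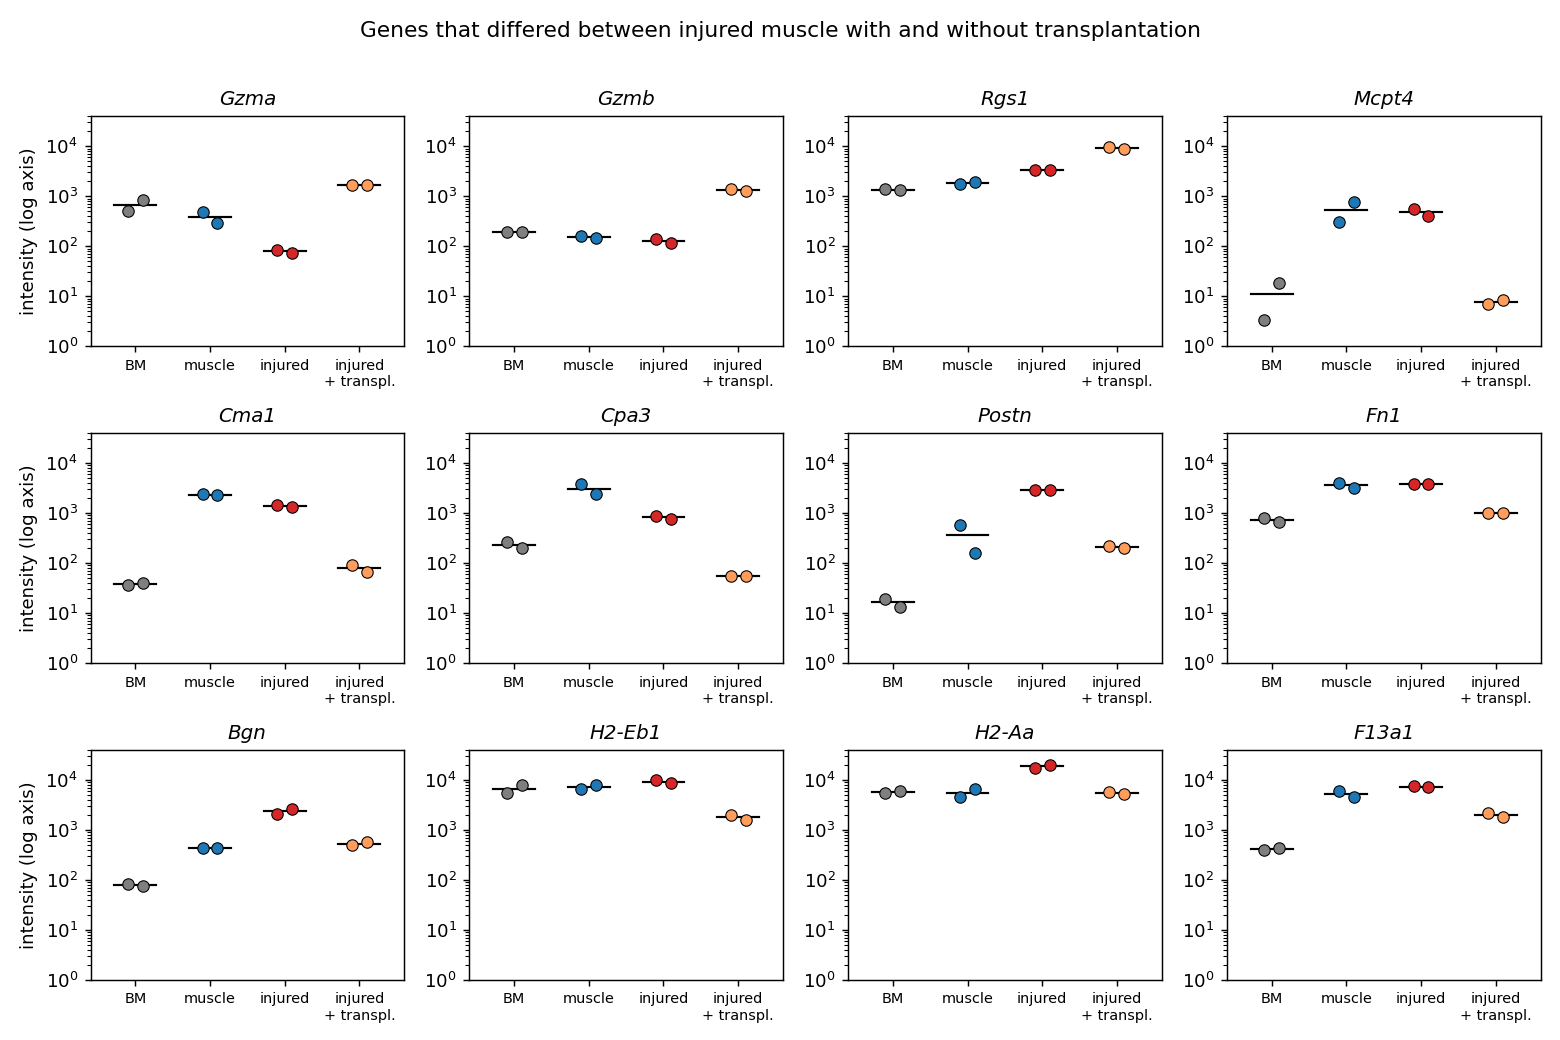
Intensity (log axis, arbitrary units) of 12 genes on each of the 8 arrays, by group; each point is an array and each line the mean of the 2 arrays of a group. Gzma and Gzmb are highest in transplanted injured muscle, at 1660 and 1319, where the mast cell proteases Cma1 and Cpa3 are at 79.6 and 54.7.

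Of 16289 probe sets 4 were higher with a transplant and 37 lower (4 and 27 genes) by limma at an adjusted p of 0.05, 9.76% higher, and 1425 had an unadjusted p under 0.05. The median log2 fold change of all probe sets was 0.00, which median centring moved to 0.14. With quantile normalization 2 were higher and 7 lower, 22.2% higher, and 9 of the 41 were kept, which among the named genes were Gzma, Gzmb, Mcpt4, Cma1, Cpa3 and H2-Eb1. The replicate block kept 15 of the 41, 2 higher and 13 lower. Median centring gave 20 lower, with Fn1, Bgn, F13a1, Postn and Myl1 no longer called; array weights gave 170 and 641, and only the 4 arrays compared 369 and 756, each keeping all 41. Pseudocounts at the 25th percentile and median gave 56 and 75 lower (the latter added after the data were seen). No filter left 2 higher. Leaving out either array of either injured group, limma called 0 and 0, with an unadjusted p under 0.05 for 1071 and 1009 probe sets without Muscle_Ctx_BMT replicate 1 or 2, and for 1012 and 961 without Muscle_Ctx replicate 1 or 2. Without BM replicate 1 or 2 the counts were 2 and 6, without Muscle replicate 1 they were 27 and 218, and without Muscle replicate 2 28 and 240. In member ranges, 0 to 19 fibroblast, 0 to 12 MHC class II and 0 to 14 proliferation genes were lower. So were 0 to 8 matrix remodelling, 0 to 6 mast cell and 0 to 6 muscle fibre genes. From 0 to 6 natural killer and cytotoxic genes were higher. Macrophage genes had 0 to 6 lower, alternatively activated macrophage genes 0 to 6 higher and 0 to 6 lower, neutrophil granule genes 0 to 4 higher, and cytokine and stem and progenitor genes 0 to 4 and 0 to 3 lower.

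How cells in the muscle of transplanted mice differ from those of the marrow was asked by comparing transplanted injured muscle with bone marrow. The list of cytokine and chemokine genes (17 of 24 members higher) was called higher in the muscle samples and held with an estimated correlation (adjusted p = 0.0376). The lists of macrophage (22 of 23), interferon response (14 of 21) and lysosome genes (11 of 22) were also called higher. Those of B cell (17 of 20 lower), T cell (16 of 21), neutrophil granule (12 of 16), stem and progenitor (15 of 22) and proliferation genes (18 of 26) were called lower. None of these 8 calls held with it (adjusted p = 0.0626 to 0.157 with an estimated correlation). The monocyte attractant Ccl2 had 9743 ± 141 against 94.7 ± 9.25 (log2 fold change 6.63, SE 0.22, adjusted p = 1.23e-05), and Ccl7, with 10264 ± 764, was at least 242-fold higher. Dab2, an adaptor of endocytosis, had 4852 ± 29.7 against 40.9 ± 8.31, and C1qb, a chain of complement C1q, 14952 ± 200 against 124 ± 1.86. Dntt was at least 96.1-fold lower, and the antibody heavy chain gene Igha had 83.2 ± 3.25 against 9328 ± 354 (log2 fold change -6.74, SE 0.35, adjusted p = 3.66e-05). As after injury, the groups moved together with the RNA controls: the Gapdh 3' to 5' ratio was 24.4 and 10.7 in bone marrow and 0.882 and 0.868 in transplanted injured muscle. A second probe set moved the same way in 82.4% of 454 genes called higher and 70.3% of 781 called lower.

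Of 23 monocyte and macrophage genes, 22 were higher, none lower and 1 did not pass (23 adjusted over the list alone), such as Ms4a7, at 8141 ± 949 against 152 ± 2.50, and the scavenger receptor Msr1, at 2563 ± 244 against 42.4 ± 21.7. Tested as a set, it was called higher (adjusted p = 7.27e-20; adjusted p = 0.0629 with an estimated correlation). Alternatively activated macrophage genes had 16 of 19 higher and 1 lower, the same adjusted over the list alone. Gpnmb, a glycoprotein of lipid-laden macrophages, had 7135 ± 327 and was at least 168-fold higher, and Folr2 at least 94.1-fold higher. That list's adjusted p was 1.4e-12, and adjusted p = 0.0511 with an estimated correlation. Cytokines and chemokines had 17 of 24 higher (18 adjusted over the list alone), with Ccl12 at least 102-fold higher. The list's call held (adjusted p = 5.11e-14, and adjusted p = 0.0376 with an estimated correlation). Interferon response genes had 14 of 21 higher (15 adjusted over the list alone), for example Rsad2, at 7589 ± 1225 against 1188 ± 33.1 (list adjusted p = 1.17e-09; adjusted p = 0.0698 with an estimated correlation). Lysosome genes had 11 of 22 higher (12 adjusted over the list alone), with the galactosidase Gla at 2162 ± 33.0 against 61.2 ± 6.31 (list adjusted p = 5.45e-08; adjusted p = 0.153 with an estimated correlation).

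Matrix remodelling genes had 14 of 21 members higher and 1 lower (16 and 1 adjusted over the list alone), with Tgfbi at 11116 ± 120 against 722 ± 141 and Mmp9 lower (list adjusted p = 5.5e-10; adjusted p = 0.0511 with an estimated correlation). Fibroblast and mesenchymal genes had 16 of 22 higher and 1 lower (18 and 1 adjusted over the list alone), with Col3a1 at 1827 ± 157, at least 43.1-fold higher. The median was 2.71, or 1.69 with values under 38.4 set to it (list adjusted p = 1.42e-08; adjusted p = 0.205 with an estimated correlation). Oxidative phosphorylation genes had 4 of 26 higher, the same adjusted over the list alone, with Sdhb up by 1.39 on the log2 scale (list adjusted p = 0.0373; adjusted p = 0.188 with an estimated correlation). That call was lost with quantile normalization (median 0.16 against 0.19), cyclic loess normalization (0.09), the filter at the 60th percentile, no intensity trend, array weights and the mean of all probe sets of a gene (0.06). It was also lost without BM replicate 1 (0.14), Muscle replicate 2 or Muscle_Ctx_BMT replicate 1 (0.16).

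B cell genes had 17 of 20 members lower and 1 higher (17 and 2 adjusted over the list alone), with a median log2 fold change of -5.27, or -3.85 with values under 38.4 set to it, and Ms4a1 at least 87.4-fold lower (list adjusted p = 2.88e-08; adjusted p = 0.125 with an estimated correlation). T cell genes had 16 of 21 lower, the same adjusted over the list alone, with Cd2, an adhesion molecule of lymphocytes, at 88.9 ± 4.20 against 1070 ± 22.3 (list adjusted p = 8.72e-07; adjusted p = 0.0629 with an estimated correlation). Neutrophil granule genes had 12 of 16 lower and 2 higher, the same adjusted over the list alone, with a median of -4.96, or -4.48 with values under 38.4 set to it. S100a8 had 177 ± 12.4 against 7878 ± 1405 (list adjusted p = 1.98e-05; adjusted p = 0.157 with an estimated correlation). Stem and progenitor genes had 15 of 22 lower, the same adjusted over the list alone. The progenitor marker Cd34 had 44.0 ± 2.28 against 687 ± 218, and Hoxa9, a transcription factor of progenitors, was at least 19.5-fold lower (list adjusted p = 2.69e-06; adjusted p = 0.0626 with an estimated correlation). Proliferation genes had 18 of 26 lower (21 adjusted over the list alone), with Mki67, a marker of dividing cells, at 238 ± 1.83 against 1729 ± 244 (list adjusted p = 6.15e-06; adjusted p = 0.0817 with an estimated correlation).

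Erythroid genes had 3 of 11 members lower, the same adjusted over the list alone, with the transferrin receptor (Tfrc) at 325 ± 44.0 against 1788 ± 10.8 (list adjusted p = 0.00621; adjusted p = 0.139 with an estimated correlation). Mast cell, basophil and eosinophil genes had 7 of 12 lower and 1 higher (8 and 1 adjusted over the list alone), with the basophil protease Mcpt8 at least 11.2-fold lower (list adjusted p = 0.0295; adjusted p = 0.216 with an estimated correlation). That call was lost with the filter at the 60th percentile (median -1.12 against -1.99, which was -0.23 floored), array weights, only the 4 arrays compared, and without BM replicate 2 (-1.91), Muscle replicate 1 or Muscle replicate 2. Natural killer and cytotoxic genes went both ways, with 4 of 17 higher and 9 lower (4 and 11 adjusted over the list alone), and were not called (median -1.62, adjusted p = 0.125): Gzmb had 1319 ± 103 against 193 ± 0.309, while Ifng had 54.3 ± 3.78 against 1204 ± 200. MHC class II genes had 2 of 21 higher and 7 lower, the same adjusted over the list alone (median -0.56, adjusted p = 0.375), with H2-Eb1 lower. Endothelial genes had 2 of 18 higher and 1 lower (2 and 0 adjusted over the list alone), with a median of -0.28 (0 floored) but a mean of 0.29 (adjusted p = 0.399), and skeletal muscle fibre genes 1 of 21 higher and 3 lower (0 and 3 adjusted over the list alone; median -0.28, 0 floored; adjusted p = 0.895).

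In all, 2465 of 16289 probe sets were higher in transplanted injured muscle than in bone marrow and 2832 lower (1119 and 1819 genes) by limma at an adjusted p of 0.05, 46.5% of them higher. The median log2 fold change of all probe sets was -0.19, moved to -0.08 by median centring and to -0.03 by cyclic loess normalization. The counts were 1260 and 1332 without Muscle_Ctx_BMT replicate 1, and 1257 and 1406 without Muscle_Ctx_BMT replicate 2. The lower count was 1538 without BM replicate 1 and 1695 without BM replicate 2. In member ranges, 9 to 22 proliferation, 4 to 11 natural killer and cytotoxic and 4 to 8 MHC class II genes were lower. So were 4 to 8 mast cell and 3 to 5 erythroid genes. From 1 to 4 natural killer and cytotoxic, 1 to 5 oxidative phosphorylation and 10 to 18 fibroblast genes were higher. Of the named genes, 12 and 11 lost their call without Muscle_Ctx_BMT replicate 1 or 2.

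Where the cells of injured muscle lie between bone marrow and uninjured muscle was asked with genes that differed by 1 or more on the log2 scale between 1 bone marrow and 1 uninjured muscle array (3141 genes chosen with replicate 1 and 2242 with replicate 2), measured on the arrays of the other number, with 0 for bone marrow and 1 for uninjured muscle. Untransplanted injured muscle lay at 1.06 (SD 9.7e-05, n = 2) and transplanted injured muscle at 0.804 (SD 0.0017, n = 2), with no test. The SD leaves out the choice of genes: with genes chosen in replicate 1 and in replicate 2 the arrays lay at 1.04 to 1.05 and 1.07 to 1.08 for untransplanted, and at 0.744 to 0.780 and 0.830 to 0.861 for transplanted injured muscle. For genes higher in muscle the reference difference was 1.43, against 1.08 and 1.11 on the untransplanted and 0.55 and 0.58 on the transplanted injured arrays. These are means over both choices of genes, which differed: 0.81 and 1.34 on Muscle_Ctx replicate 1, and 0.35 and 0.76 on Muscle_Ctx_BMT replicate 1. For genes lower in muscle it was -0.65 (-0.48 and -0.83 with the 2 choices), against -0.97 and -0.95 on the untransplanted and -0.98 and -1.0 on the transplanted arrays, so for these genes both injured groups lay further from bone marrow than uninjured muscle did. The RNA controls set the injured arrays apart from both reference groups. The Gapdh 3' to 5' ratio was 10.7 to 46.9 on reference arrays, whose groups overlapped, and 0.808 to 0.882 on injured ones. Beta-actin ratios did not overlap between the reference groups, at 5.75 and 5.68 in bone marrow and 19.0 and 10.1 in uninjured muscle.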

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

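The test of the cell-type lists together with its condition on the estimated correlation, the 3 tests of the share of fibroblast, endothelial and muscle fibre genes called higher, and the test of the fibroblast list without Gsn and Thy1 were chosen after the results were seen; the bounds of the other tests were written after the calls of the 4 comparisons and before those tests were run. Among control probe sets outside the comparisons, Gapdh 3' to 5' ratios were at least 10.7 on uninjured and at most 0.882 on injured arrays. For beta-actin these bounds were 5.68 and 1.23. The bacterial spike-in controls were higher on the injured arrays for 9 of 9 probe sets, with a median fold of 2.81 (1.84 to 4.49).

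The first pattern is the set of genes called between injured and uninjured muscle, where all injured arrays also differ from all uninjured ones in the 3' to 5' ratios. Unlike intensity distributions are argued against as the whole cause, as 90.6% of calls stayed in the same direction after quantile normalization. A level difference was not tested. A difference in coverage along the transcript may account for part of the calls. A second probe set moved the same way in 72.1% of genes called higher and 66.3% called lower (bounds: 60% for coverage, 80% against). Across genes, changes of 2 probe sets correlated at 0.363 (0.696 for muscle against bone marrow). Of 14 cell-type lists 10 were called but none held with an estimated correlation, which leaves coverage open too. Coverage and injury, named by the design, cannot be told apart, as they fall on the same arrays.

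The second pattern is the rise of fibroblast, endothelial and muscle fibre genes in uninjured muscle against bone marrow, where of the 3 list calls only the endothelial one held with an estimated correlation (adjusted p = 0.0376, against 0.101 for fibroblast and 0.0844 for muscle fibre genes). The coverage of Muscle replicate 1, the array with the highest Gapdh ratio, is argued against as the cause for the fibroblast list, whose median was 3.10 without that array against 3.85. Cells without CD45, or their RNA, are a hypothetical source that stays open: 90.9% of 22 fibroblast (8 of 22 with only the 4 arrays compared), 61.1% of 18 endothelial and 42.9% of 21 muscle fibre genes were called higher, but these shares restate the pattern, and expression in CD45+ cells would give them too, so the 2 cannot be told apart. The most abundant genes included Col1a2 at 6756, Col3a1 at 4578, Dcn at 4017, Fabp4 at 5311, Tnnc2 at 1324 and, chosen after their values were seen, Acta1 at 328 and 800 and Ckm at 127 and 1296 on the 2 arrays; isolation by CD45 would remove such cells, both bone marrow arrays were at or above the filter value for 7, 8 and 7 members of the 3 lists, and 0, 2 and 0 members are in another list. The tissue itself, as named by the design, stays open as an untested explanation.

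The third pattern is the call of the fibroblast list as lower in transplanted injured muscle, where 2 of 22 members passed, 0 without any 1 of the injured arrays, and the call did not hold with an estimated correlation (adjusted p = 0.106). Unlike distributions of intensities are argued against, as the median of the list was -2.09 after quantile normalization and -2.16 before. Both give all arrays a common level, so a difference in level was not tested. A smaller share of fibroblast-like cells would lower all members by a common factor, and this is argued against for the 22 members, whose log2 fold changes had a variance 7.35 times that of their error, ranging from -2.77 to 0.91 for Gsn. Gsn and Thy1 (-0.79), both chosen after their values were seen, are also expressed by other cells; without them this variance ratio was 2.18 over 20 members, from -2.77 to -1.39, between the bounds of 2 and 4, so a smaller share may still account for these and cannot be told apart from a change within the cells. Transplantation itself, which the design names, was not tested as a cause.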

How the results depend on the processing

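The pseudocount at the median was chosen after the data were seen; the other tests were planned. Over all alternatives the named genes gave 8998 results with the same direction and side of the threshold, 661 weaker, 236 stronger and 0 reversed, and the lists 2132, 117, 37 and 2. Bone marrow and uninjured muscle replicates (n = 2) differed more (SD 0.331 and 0.451) than injured ones (0.183 and 0.189). With 1 spread, the fit may call too many for muscle against bone marrow and too few with a transplant.

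Probe sets higher and lower with a transplant after injury (4 and 37) were 2 and 7 with quantile normalization, 20 lower with median centring, 56 lower with the pseudocount at the 25th percentile, 11 and 75 at the median, 2 higher with no filter, 170 and 641 with array weights, 369 and 756 with only the 4 arrays compared, 2 and 13 with the replicate block, and in limma 0 and 0 at a threshold of 0.01, where 1425 had an unadjusted p under 0.05. For muscle against bone marrow (787 and 204) they were 440 and 38 with array weights, 266 and 22 with only the 4 arrays compared, 414 and 34 at a threshold of 0.01, and 340 lower with the pseudocount at the median. For injured against uninjured muscle (1973 and 2262) 1172 were lower with array weights, and the counts were 1044 and 1027 with only the 4 arrays compared and 811 and 735 at a threshold of 0.01. For transplanted injured muscle against bone marrow (2465 and 2832) they were 1358 and 1261 at that threshold, which calls fewer by construction. Other causes were not tested.

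Leaving out 1 array gave 466 to 1257 higher and 43 to 1864 lower for muscle against bone marrow, 609 to 3287 and 706 to 2780 for injured against uninjured muscle, 0 to 28 and 0 to 240 with a transplant, and 1257 to 3360 and 1332 to 3845 for transplanted injured muscle against bone marrow. The 0 and 0 came without an injured array, where 961 to 1071 probe sets had an unadjusted p under 0.05. For muscle against bone marrow, counts moved by over 1.5 times without BM replicate 1 (468 and 43) or 2 (466 and 60), without Muscle replicate 1 (387 lower) or 2 (1257 and 1864), and for lower ones without Muscle_Ctx_BMT replicate 1 or 2 (98 and 99) or Muscle_Ctx replicate 1 or 2 (86 and 84). For injured against uninjured muscle they moved without Muscle_Ctx replicate 1 (617 and 706) or 2 (609 and 844) and Muscle replicate 2 (3287 higher). With a transplant they moved without any array: 2 and 6 without either BM array, 27 and 218 without Muscle replicate 1, and 28 and 240 without Muscle replicate 2. For transplanted injured muscle against bone marrow they moved without Muscle_Ctx_BMT replicate 1 (1260 and 1332) or 2 (1257 and 1406) and BM replicate 1 (1538 lower) or 2 (1695 lower). The cause was not tested. Leaving out an injured array moved the position by less than 0.01.

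The position between BM and muscle of Muscle_Ctx and Muscle_Ctx_BMT (1.06 and 0.804) was 1.07 and 0.831 with quantile normalization, 1.08 and 0.855 with cyclic loess, 1.03 and 0.785 with median centring, 1.07 and 0.821 with a pseudocount of 1, 1.05 and 0.780 at the 25th percentile, 1.06 and 0.806 at the median, 0.963 and 0.684 with no filter, 1.27 and 1.07 with the filter at the 60th percentile, and 0.866 and 0.560 for a log2 difference of 2 or more. Transplanted lay under untransplanted in each. The cause was not tested. The ribosomal protein list for transplanted injured muscle against bone marrow, uncalled with a median of 0.10, was called lower at -0.59 with quantile and -0.46 with cyclic loess normalization; the cause was not tested.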

Other observations

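Of the tests in this part only the pseudocount at the median was chosen after the results were seen. The 3' to 5' ratios of the RNA controls also differed between all injured and all uninjured arrays, so they moved with each change given here between such groups. Immediate early and stress genes had 2 of 26 members higher and 7 lower after injury (3 and 11 adjusted over the list alone; adjusted p = 0.158). Hspa1a, a heat shock protein, had 909 ± 86.3 after injury against 4149 ± 4.62, Hsph1, a helper of that protein, 303 ± 11.5 against 2470 ± 456, and the transcription factor Klf6 1508 ± 11.3 against 3637 ± 29.1, with both other Klf6 probe sets moving the opposite way. The list was called lower with quantile (median -0.86 against -0.56) or cyclic loess normalization (-0.80) and without Muscle replicate 1 (-0.72). In transplanted injured muscle against bone marrow 7 members were higher and 4 lower (8 and 5 adjusted over the list alone; median 0.09, adjusted p = 0.0534), with Ier3 at 6737 ± 57.7 against 943 ± 198, and the list was called higher with median centring (0.19), a pseudocount at the 25th percentile or the median, no filter, the replicate block or the mean of all probe sets of a gene (median 1.02), and without BM replicate 2 (0.40), Muscle_Ctx_BMT replicate 1 (0.16) or either Muscle_Ctx array. Glycolysis and hypoxia genes had 4 of 21 higher and 3 lower after injury, the same adjusted over the list alone, with a median of 0.00, a mean of -0.15 and adjusted p = 0.746. The glucose transporter Slc2a3 had 93.9 ± 17.6 against 1174 ± 57.5, and the triose phosphate isomerase Tpi1 2136 ± 234 against 1016 ± 148. Against bone marrow, Slc2a3 fell by 5.23 on the log2 scale in transplanted injured muscle, where the list had 5 higher and 6 lower, the same adjusted over the list alone (median 0.20, mean -0.32, adjusted p = 0.613).

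Homing and adhesion genes were not called in any comparison, although single members moved: the integrin Itgb7 had 479 ± 22.8 in transplanted injured muscle against 2912 ± 161 in bone marrow, and the chemokine receptor Ccr1 2158 ± 160 against 246 ± 108 (7 of 20 higher and 5 lower; 10 and 8 adjusted over the list alone; adjusted p = 0.331). After injury 4 were higher and 1 lower (4 and 3 adjusted over the list alone; median -0.01, mean 0.05, adjusted p = 0.352), and in uninjured muscle against bone marrow 3 were higher and 1 lower (4 and 3 adjusted over the list alone; adjusted p = 0.613), with the chemokine Cxcl12 at least 16.7-fold higher. The p53 targets had 3 of 16 higher and 2 lower in transplanted injured muscle against bone marrow, the same adjusted over the list alone (median -0.13, -0.03 floored; adjusted p = 0.518, with the test upwards), with Cdkn1a, which halts the cell cycle, at 3218 ± 466 against 496 ± 298 and Trp53inp1 at 130 ± 20.7 against 1230 ± 310, with a second probe set that moved the opposite way. Ribosomal proteins had 1 higher and 1 lower of 16 after injury, the same adjusted over the list alone, Rps19 at 6141 ± 1026 against 2805 ± 0.495 and Rpl12 at 28.1 ± 23.3 against 290 ± 33.7 (median 0.34, adjusted p = 0.0613), and the list was called higher without Muscle_Ctx replicate 2 (0.33), without Muscle_Ctx_BMT replicate 1 or 2, with only the 4 arrays compared and with median centring (0.49). In uninjured muscle against bone marrow 0 of 16 ribosomal protein genes were called by limma (1 lower at an unadjusted p under 0.05; median -0.04, adjusted p = 0.613), and the list was called lower with cyclic loess normalization (-0.24). Oxidative phosphorylation had 0 of 26 called by limma in that comparison (1 lower at an unadjusted p under 0.05; median -0.14, adjusted p = 0.375). Megakaryocyte genes had 2 of 11 higher in transplanted injured muscle against bone marrow, the same adjusted over the list alone, Pf4 and Ppbp, with a median of -0.40 (0 floored) and a mean of 0.04 (adjusted p = 0.554), and satellite and myogenic genes 1 of 9 lower, Notch3 (0 adjusted over the list alone), with a median of -0.51 (0 floored) and the test upwards (adjusted p = 0.872). Of the sex-linked genes, the sex of the mice not being given in the sources used here, group means were 20.9 to 87.5 for Xist, 295 to 543 for Eif2s3y, 48.4 to 155 for Kdm5d and 49.3 to 70.0 for Uty; Xist was lower after injury (adjusted p = 0.0126) and Kdm5d lower in transplanted injured muscle than in bone marrow (adjusted p = 0.0302). Member ranges after injury, higher and lower, were 0 to 6 and 5 to 14 for immediate early and stress genes. They were 0 to 7 and 2 to 6 for glycolysis and 0 to 4 and 1 to 3 for ribosomal proteins. For homing they were 0 to 5 and 0 to 3. In transplanted injured muscle against bone marrow they were 6 to 10 and 2 to 7 for immediate early and stress genes, 0 to 8 and 3 to 8 for glycolysis, 2 to 10 and 2 to 8 for homing, and 1 to 3 and 1 to 3 for p53 targets. Megakaryocyte genes there had 1 to 3 higher, and homing genes in uninjured muscle against bone marrow 1 to 7 higher and 1 to 4 lower.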
